A study of Mus musculus with 12 samples.

How the data were processed

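Total RNA of 12 samples of sorted mouse bone marrow cells was measured on Affymetrix expression arrays after biotin labelling. Per the labels' protocols the cells were taken fresh and untreated, RNA was extracted with the RNeasy Micro kit, and it was amplified and labelled by the array maker's protocol. Per the labels, the CLP gate excluded cells with CD3E, CD11C, CD19, LY6C, TER119, NK1.1, MAC1 or GR1, and took cells with high FLT3, IL7R, low SCA1 and low KIT, with or without LY6D. The proB gate took CD19 and B220 positive, KIT positive cells without surface IgM, IgD or CD25 and excluded GR1, MAC1, CD3E and NK1.1. A free-text label of the LY6D-positive CLP samples calls them LY6D-negative. Title, source name and gate call them positive and were followed, and the Ly6d signal averaged 9.98 to 10.86 in these arrays and 4.99 in the LY6D-negative ones.

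The deposited table held 1 intensity per probe set and array. Per the submitters' processing notes the authors made the values with RMA (robust multi-array average), whose version, probe set definition and software are not given in the sources used here. RMA subtracts background, quantile-normalizes the arrays and sums up the probes of a probe set. The deposited intensity is on a linear scale, as the values show: array maxima lay between 17364.9 and 21662 and array medians between 28.12 and 29.28. Because such normalization forces like distributions on all arrays, a change of most genes in one direction could not be seen. No detection calls were used, and genes near the low end of the scale have compressed fold changes.

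The table had 17370 probe sets. Of these 64 were array controls, 16464 had 1 gene symbol, none had several, and 842 had none in the annotation table used here and were left out of the gene tests. Among the genes unnamed here are Cd19 and Cd79a. All 16464 symbols equalled the current RefSeq symbol of their Entrez identifier (assembly GRCm38.p6, used for names only). Each gene had 1 probe set, so averaging probe sets could not be tried. No coordinates are printed because no source names the build behind the probe sets.

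Intensities were taken to log2 and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 12 arrays, which left 6 residual degrees of freedom to which empirical Bayes added 4.45 of prior. Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over the 16464 genes, with a threshold of 0.05. The contrasts were EBF1-deficient minus Ebf1 wild type, FOXO1-deficient minus Foxo1 wild type, LY6D-positive minus LY6D-negative CLP, proB minus LY6D-positive CLP (both of the Foxo1 wild type where CLP), Ebf1 minus Foxo1 wild type, and the difference of the knock-out effects. The contrasts of stages, of wild types, of FOXO1 and of the knock-out difference share the Foxo1 wild-type LY6D-positive arrays. Those of EBF1, of wild types and of the difference share the Ebf1 wild-type ones. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these arrays, which may be technical outside the proB pair. The proB replicates had opposite Xist and Eif2s3y signals, which argues against a purely technical spread there. Groups, contrasts, tests, gene lists, alternatives and the rule for named genes were set before the data were examined.

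Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 19 lists of a contrast. Over 114 tests 54 passed with the preset and 21 with the estimated correlation. The lists covered B-lineage specification, pre-B-cell receptor parts, V(D)J recombination, lymphoid regulators, FOXO targets, T, NK, granulocyte and monocyte, dendritic, erythroid, stem, and mature B and plasma cell genes, cell cycle, interferon response, immediate early genes, glycolysis, apoptosis and p53, ribosomal proteins and sex chromosome genes. Median, mean and test agreed in sign for all 54 passing results, and differed for 18 of the other 60. Only 11 of 37 ribosomal protein genes were measured. Stage sets were the genes past the threshold in the contrasts of stages, in the fit of all 12 arrays. Overlaps were set against n1 × n2 / N and tested with Fisher's exact test over genes.

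Named genes were Ebf1 and Foxo1 throughout, 22 anchor genes of early B-cell development (20 measured), the 8 largest positive and negative changes past the threshold in each contrast (6 for the difference), up to 4 members with the smallest p of each passing list, and 8 shared genes per direction. Predicted and clone-named genes, olfactory and vomeronasal receptors, small RNAs and single immunoglobulin or T-cell receptor segments were left out. List members named because they passed the threshold but fall outside that rule, such as Cd5 or Irf4, were chosen after their values were seen.

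The steps were tested on simulated data for the EBF1 contrast over 16464 genes. Of 100 genes changed 2-fold 65% were recovered, and of 100 changed 4-fold 99%, with 8 calls among unchanged genes. In limma's camera test a shifted list of 20 genes was recovered, and 4 of 100 unchanged lists passed at 0.05 before adjustment. The simulated genes were independent of each other, whereas the estimated correlation reached 0.273 in a real list. The simulation therefore does not test the list results under correlation between genes. Alternatives were leaving out dim genes (below the lower quartile, or below the median), median centring, quantile normalization, all probe sets, fitting the compared arrays alone, the replicate number as a block, array weights, an intensity trend with robust moderation, a 2-fold minimum, other control groups, an estimated correlation, stage sets from arrays outside the knock-out comparison (added after seeing the data), and leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.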

Results

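Gene expression was measured in progenitor cells that were sorted by flow cytometry from mouse bone marrow, with 1 Affymetrix array for each of 12 RNA samples. Common lymphoid progenitors (CLP) are early cells that can still become B, T or NK cells, and surface LY6D marks those of them that have begun to take the B-cell path. The 6 groups held 2 arrays each. They were LY6D-negative CLP from Foxo1 wild-type mice, LY6D-positive CLP from Foxo1 wild-type and Foxo1-deficient mice, LY6D-positive CLP of the Ebf1 wild-type and Ebf1-deficient line, and wild-type proB cells, which carry CD19 and B220 but no surface IgM or IgD. EBF1 and FOXO1 are transcription factors needed for B-cell development, and the series set cells lacking either against their own wild type and along the normal sequence of stages. Ebf1-deficient marrow came, per the series text, from irradiated hosts that had received Ebf1-deficient progenitors. Whether the Ebf1 wild-type marrow also came from transplanted hosts is not given in the sources used here. Signals are given as log2 of the deposited intensity, which ran from 1.64 to 14.4 over the 16464 genes, and changes as log2 differences with their standard error (SE) from limma. The number of arrays, 2 per group, limits the precision. Replicates correlated at 0.984 to 0.995 across genes, and no pair was identical.

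Foxo1 signal was 8.16 ± 0.18 (SD, n = 2) in wild-type and 3.75 ± 0.29 (SD, n = 2) in Foxo1-deficient LY6D-positive CLP, and so fell by 4.41 (SE 0.17, limma adjusted p = 1.2e-06). Ebf1 signal was 9.02 ± 0.02 (SD, n = 2) in Ebf1 wild-type and 7.90 ± 0.24 (SD, n = 2) in Ebf1-deficient cells, and fell by 1.12 (SE 0.22, limma adjusted p = 0.041). Each factor's transcript was also lower when the other factor was missing. Ebf1 fell by 2.48 (SE 0.22, limma adjusted p = 0.00034) in Foxo1-deficient cells, and Foxo1 fell by 2.02 (SE 0.17, limma adjusted p = 0.00027) in Ebf1-deficient cells. Along the normal sequence both rose. Ebf1 went from 5.05 ± 0.45 (SD, n = 2) in LY6D-negative CLP to 9.10 ± 0.03 (SD, n = 2) in LY6D-positive CLP and 10.53 ± 0.22 (SD, n = 2) in proB cells, and Foxo1 from 5.84 ± 0.16 (SD, n = 2) to 8.16 and then 8.99 ± 0.07 (SD, n = 2). Where the probes lie relative to the deleted part of either gene is not given in the sources used here, so the remaining Ebf1 signal does not test the deletion. The Ebf1 call in its own knock-out ended when any 1 of the 8 LY6D-positive arrays was left out, with log2 differences from -1.30 to -0.95.

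**Figure D1:**
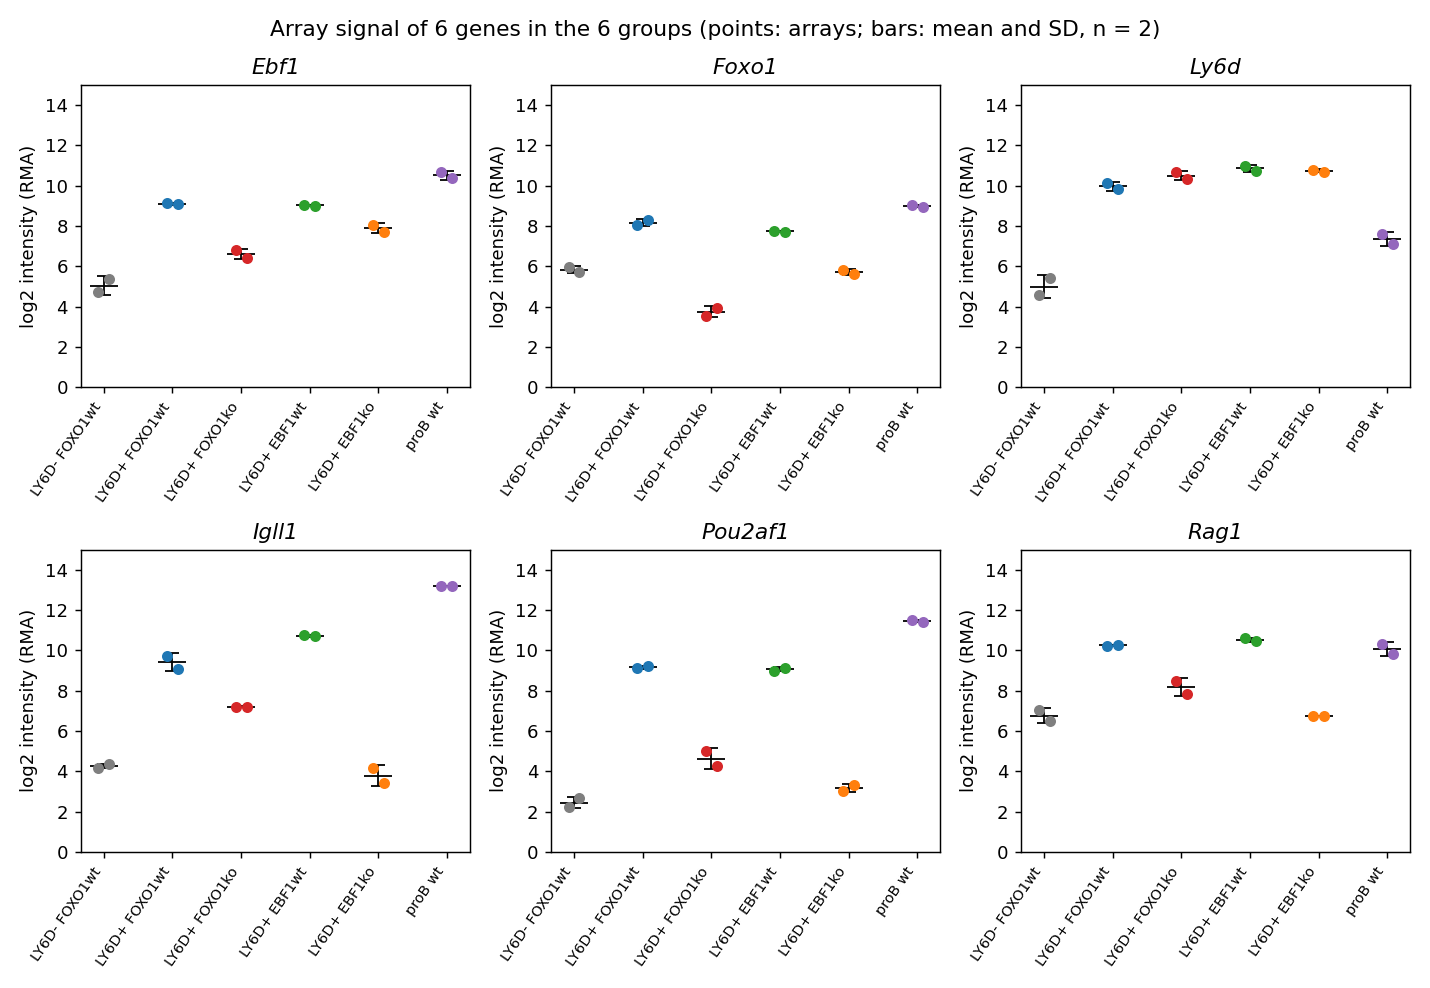
Log2 array signal (y axis) of Ebf1, Foxo1, Ly6d, Igll1, Pou2af1 and Rag1 in each of the 6 groups (x axis). Points are arrays and bars show the mean and SD of 2 arrays. Igll1 averaged 10.73 in Ebf1 wild-type and 3.79 in Ebf1-deficient LY6D-positive CLP, while Ly6d averaged 10.86 and 10.74 in the same groups.

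The first step of the normal sequence, from LY6D-negative to LY6D-positive CLP of Foxo1 wild-type mice, raised early B-lineage genes. Pou2af1, a coactivator of immunoglobulin gene transcription, rose by 6.70 (SE 0.23). Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B-cell receptor, rose by 5.15 (SE 0.24) and 4.60 (SE 0.18). Ebf1 itself rose by 4.05 (SE 0.22) and Rag1, part of the recombinase that joins V, D and J segments, by 3.48 (SE 0.24). Gpat3 and Gimap4 rose by 4.47 (SE 0.18) and 4.18 (SE 0.42). Ly6d rose by 4.99 (SE 0.27), but it was the gene the cells were sorted on. The germ-cell helicase Ddx4 fell by 4.80 (SE 0.18), the myeloid protease gene Prtn3 by 2.71 (SE 0.37), the regulator Nfil3 by 2.49 (SE 0.36) and the stem-cell surface gene Cd34 by 1.49 (SE 0.13). Chil3, Anxa3, Plscr1, Usp46 and Wfdc17 also fell, by between 3.32 and 1.84. Pax5, with a log2 difference of 0.56 (SE 0.37), did not pass the test, nor did Dntt, Flt3, Kit, Tcf3, Ikzf1, Spi1, Gata3 or Notch1. In all, 186 of 16464 genes changed at an adjusted p under 0.05 in limma, 123 higher and 63 lower, and 121 of them by at least 2-fold.

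Of the 21 measured members of the B-lineage list 14 rose and none fell between the CLP stages (17 when adjusted over the list alone), with a median of 1.59 (adjusted p = 1.09e-39, limma camera, and 0.000543 with an estimated correlation). Blk, a kinase of B-cell receptor signalling, rose by 3.09 (SE 0.16) and Cd79b, a signalling chain of that receptor, by 1.62 (SE 0.13). The list of pre-B-cell receptor parts had 6 of 12 members higher, 7 adjusted over the list alone, and its adjusted p was 0.00399 with an estimated correlation. The stem and multipotent progenitor list shifted down with a median of -0.43. Cd34 and Mycn were the 2 of its 17 members that fell, 9 did so adjusted over the list alone, and its adjusted p was 0.00399 with an estimated correlation. Another 5 lists passed with the preset correlation and not with an estimated one. Rag1, Rag2 and Xrcc6 rose among the 12 recombination genes (adjusted p = 0.248 with an estimated correlation), and Rag1, Rag2 and Il7r among the 24 FOXO target genes (adjusted p = 0.101 with an estimated correlation), of which 6 rose adjusted over the list alone. Prtn3 and Csf3r fell among the 18 granulocyte and monocyte genes, 5 did so adjusted over the list alone, and the adjusted p was 0.234 with an estimated correlation. Without LY6D-negative replicate 2, whose neutrophil-gene median was 7.69 against 5.35 in replicate 1, this list's median went from -0.589 to -0.267 and its call ended with the preset correlation as well (adjusted p = 0.058). The glycolysis list (median -0.25) and the ribosomal protein list (median -0.14) had no member past the threshold over all genes, and adjusted p of 0.0835 and 0.308 with an estimated correlation. The other 11 lists did not pass, with adjusted p from 0.123 for apoptosis and p53 to 0.777 for erythroid and megakaryocyte genes. The apoptosis and p53 list passed upward without genes below the median signal (adjusted p = 0.0143), and the NK and innate lymphoid list upward without Foxo1 wild-type LY6D-positive replicate 1 (adjusted p = 0.0484). Without either array of LY6D-positive CLP the 186 genes became 61 or 63 (replicates 1 and 2), and without LY6D-negative replicate 2 they became 64. With the Ebf1 wild-type arrays standing for LY6D-positive CLP the count was 846.

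The second step, from LY6D-positive CLP to proB cells, changed many more genes. Igkc, the constant part of the kappa light chain, rose by 7.33 (SE 0.46), the transcription factor gene Lef1 by 5.62 (SE 0.25), the peptidase gene Enpep by 5.71 (SE 0.90) and the kinase gene Sgk1 by 5.40 (SE 0.60). Sertad4, F13a1, Plxdc1 and Jchain rose by between 5.17 and 4.81. Pax5, which fixes B-cell identity, rose by 2.33 (SE 0.37), Igll1 by 3.79 (SE 0.24), Vpreb1 by 3.35 (SE 0.18) and Tcf3, which encodes E2A, by 1.15 (SE 0.14). Cd34 fell by 6.41 (SE 0.13), the cytokine receptor gene Il18r1 by 6.22 (SE 0.34), and Flt3, whose product was part of the CLP gate, by 4.65 (SE 0.12). Chdh, Ptger2, Mpeg1, Gbp8, Slc35d3 and Gpr25 fell by between 6.20 and 4.85, and Notch1 fell by 1.97 (SE 0.16). Dntt fell by 0.68 (SE 0.12), whereas Rag1 and Rag2 differed by -0.19 (SE 0.24) and -0.11 (SE 0.16) and did not pass. In limma 2502 genes changed, 1087 higher and 1415 lower, and 1182 of them by at least 2-fold. Leaving out either LY6D-positive array gave 1594 (replicate 1) or 1561 (replicate 2).

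In proB cells 16 of 21 B-lineage genes were higher and Blk and Dntt lower than in LY6D-positive CLP (16 and 3 adjusted over the list alone), with a median of 1.54 (adjusted p = 1.5e-10, limma camera, and 0.0113 with an estimated correlation). Cplx2 rose by 4.03 (SE 0.13) and Vpreb3 by 3.90 (SE 0.20). Cell-cycle genes shifted up with a median of 0.97 and 24 of 27 members positive, and 16 of them rose past the threshold (16 adjusted over the list alone, adjusted p = 0.0169 with an estimated correlation). Among them E2f2 rose by 2.74 (SE 0.15), Ccna2 by 1.75 (SE 0.18), Rrm2 by 1.67 (SE 0.16) and Cdk1 by 1.19 (SE 0.13). Of 17 stem and multipotent progenitor genes 9 fell, 12 adjusted over the list alone (adjusted p = 0.0113 with an estimated correlation), including Cd27 by 3.11 (SE 0.25), Hoxa5 by 2.70 (SE 0.24) and Meis1 by 2.11 (SE 0.18). Of 14 dendritic and plasmacytoid genes 6 fell, 8 adjusted over the list alone (adjusted p = 0.0169 with an estimated correlation), including Cox6a2 by 4.20 (SE 0.18), Tlr7 by 2.53 (SE 0.24) and Siglech by 2.15 (SE 0.22). CD11C, a dendritic surface protein, had been used to clear the CLP gate.

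The remaining lists that passed between LY6D-positive CLP and proB cells lost their call with an estimated correlation. Pre-B-cell receptor genes had 6 members higher and 2 lower of 12 (adjusted p = 0.077 with an estimated correlation). NK and innate lymphoid genes had 6 lower and 1 higher of 18, with Klrd1 down by 4.07 (SE 0.21) and Nkg7 by 3.67 (SE 0.17). Adjusted over the list alone 7 were lower and 1 higher (adjusted p = 0.0579 with an estimated correlation). Granulocyte and monocyte genes had 3 of 18 lower, Mpo, Cebpb and Csf1r, of which Mpo fell by 4.27 (SE 0.62) (adjusted p = 0.304 with an estimated correlation). Interferon response genes had 5 lower and 1 higher of 18, with Mx1 down by 1.95 (SE 0.26). Adjusted over the list alone 8 were lower and 2 higher (adjusted p = 0.304 with an estimated correlation). Immediate early genes had 4 of 19 lower, with Fos down by 3.71 (SE 0.68). Adjusted over the list alone 6 were lower and 2 higher (adjusted p = 0.39 with an estimated correlation). Glycolysis genes had 4 lower and 1 higher of 14, and ribosomal protein genes 4 lower of 11, with adjusted p = 0.12 with an estimated correlation for both. Car2 was the 1 of 13 erythroid genes that rose (adjusted p = 0.077 with an estimated correlation). The other 7 lists did not pass. Among these, 6 lymphoid regulators rose and 10 fell of 22 (adjusted p = 0.2), and 5 FOXO target genes rose and 7 fell of 24 (adjusted p = 0.184).

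In EBF1-deficient LY6D-positive CLP genes of the pre-B-cell receptor, of the recombinase and of the B-cell path were lower than in the Ebf1 wild type. Transplantation stays open as a contribution to this comparison. Igll1 fell by 6.94 (SE 0.24), Pou2af1 by 5.90 (SE 0.23), Rag1 by 3.78 (SE 0.24), Vpreb1 by 3.39 (SE 0.18) and Vpreb3 by 3.30 (SE 0.20). Gpat3, Mzb1 and Gimap4 fell by 3.55, 3.34 and 3.29. Cd79b fell by 1.79 (SE 0.13), Rag2 by 1.23 (SE 0.16) and Blnk, an adaptor of the pre-B-cell receptor, by 1.01 (SE 0.17). Igkc rose by 4.12 (SE 0.46), Socs2, a feedback inhibitor of cytokine signalling, by 3.94 (SE 0.40), Havcr2 by 2.64 (SE 0.30) and the receptor gene Lrp1 by 2.21 (SE 0.16). The neutrophil surface gene Cd177 rose by 2.29 (SE 0.22), Slfn4 by 2.26 (SE 0.37), the red-cell carbonic anhydrase gene Car1 by 2.0 (SE 0.21) and the granule protease gene Ctsg by 2.0 (SE 0.39). Several lymphoid genes did not pass the test, with log2 differences of 0.02 (SE 0.12) for Dntt, -0.12 (SE 0.27) for Ly6d, -0.11 (SE 0.12) for Flt3, 0.07 (SE 0.14) for Ikzf1 and -0.57 (SE 0.15) for Il7r. Pax5 was near the low end of the scale in both groups, at 3.26 ± 0.09 and 3.50 ± 0.15 (SD, n = 2). In limma 189 genes changed, 63 higher and 126 lower, and 124 of them by at least 2-fold. The count was 92 or 77 without EBF1-deficient replicate 1 or 2, 70 or 66 without Ebf1 wild-type replicate 1 or 2, and 86 when these 4 arrays were fitted alone. Against the mean of both wild-type groups it was 836.

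Of 21 B-lineage genes 15 fell and none rose without EBF1 (16 adjusted over the list alone), with a median of -1.16 (adjusted p = 1.15e-35, limma camera, and 0.000743 with an estimated correlation). Ebf1, the targeted gene, belongs to this list and was among the 15. Of 12 pre-B-cell receptor genes 7 fell, 8 adjusted over the list alone (adjusted p = 0.00255 with an estimated correlation). Rag1 and Rag2 were the recombination genes that fell (2 of 12, and 3 adjusted over the list alone, adjusted p = 0.0394 with an estimated correlation). They also belong to the FOXO target list, where Pik3ip1 fell by 1.25 (SE 0.18) and Txnip by 0.81 (SE 0.14), and 5 of 24 members fell in all (9 adjusted over the list alone, adjusted p = 0.0306 with an estimated correlation). Of 19 immediate early genes Egr1 fell by 2.83 (SE 0.28), Klf4 fell by 1.29 (SE 0.20) and Btg2 fell by 1.23 (SE 0.20), and 9 fell adjusted over the list alone (adjusted p = 0.042 with an estimated correlation). Cell-cycle genes shifted up with a median of 0.27 and 25 of 27 members positive, but Ccne2 alone passed over all genes and over the list alone (adjusted p = 0.0306 with an estimated correlation). The mature B and plasma cell list had a median of -0.18 and no member past the threshold over all genes (1 adjusted over the list alone, adjusted p = 0.0394 with an estimated correlation).

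Among lists of other cell types, Car1 and Alas2 were the erythroid genes that rose (2 of 13, and 4 adjusted over the list alone, adjusted p = 0.0251 with an estimated correlation). Without genes below the median signal the erythroid list's median went from 0.467 to 0.025 and its call ended (adjusted p = 0.859). Ctsg and Lyz2, a lysozyme of myeloid cells, were the granulocyte and monocyte genes that rose (2 of 18, and 3 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation). The dendritic list had a median of 0.16 and no member past the threshold over all genes (adjusted p = 0.0796 with an estimated correlation). The median of 7 neutrophil genes (S100a8, S100a9, Ngp, Camp, Ltf, Lcn2 and Chil3, chosen after their values were seen) was 9.76 and 9.77 in the EBF1-deficient arrays, 8.17 and 7.93 in their wild type, and 5.39 and 5.55 in the Foxo1 wild type. Their log2 differences without EBF1 ran from 1.23 to 2.65, and none of the 7 passed the test. The other 9 lists did not pass, among them stem and multipotent progenitor genes (adjusted p = 0.202), of which Cd34, Mycn and Cd48 rose, and T-lineage genes (adjusted p = 0.94). Without either proB array the apoptosis and p53 list and the sex chromosome list passed downward (adjusted p = 0.0289 and 0.0284).

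Loss of FOXO1 in LY6D-positive CLP lowered B-lineage genes as well. Pou2af1 fell by 4.52 (SE 0.23), Gimap4 and Gimap8, GTPases of lymphocytes, by 4.39 (SE 0.42) and 3.48 (SE 0.20), Jun by 2.86 (SE 0.53), Pde2a by 2.69 (SE 0.16) and Ms4a4b by 2.58 (SE 0.27). Igll1 fell by 2.21 (SE 0.24), Rag1 by 2.08 (SE 0.24), Blnk by 1.73 (SE 0.17), Rag2 by 1.38 (SE 0.16), Vpreb1 by 1.37 (SE 0.18) and Il7r, the receptor chain for interleukin 7, by 1.16 (SE 0.15). Socs2 rose by 3.56 (SE 0.40), Jchain, which joins secreted IgM chains, by 3.34 (SE 0.63), Ctsg by 3.0 (SE 0.39) and the T-cell surface gene Thy1 by 2.54 (SE 0.31). Klhl30, Ddx4, Lrp1 and Ifitm1 rose by between 2.50 and 2.29. Dntt, Flt3, Kit, Ikzf1 and Tcf3 did not pass, and neither did Ly6d at 0.53 (SE 0.27). In limma 369 genes changed, 152 higher and 217 lower, and 211 of them by at least 2-fold. The count was 113 or 104 without FOXO1-deficient replicate 1 or 2, 189 or 127 without Foxo1 wild-type replicate 1 or 2, and 845 with array weights.

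Of 21 B-lineage genes 13 fell and none rose without FOXO1 (15 adjusted over the list alone), with a median of -1.36 (adjusted p = 3.17e-21, limma camera, and 0.00331 with an estimated correlation). Foxo1, the targeted gene, belongs to this list and was among the 13. Of 12 pre-B-cell receptor genes 8 fell, also 8 adjusted over the list alone (adjusted p = 0.00903 with an estimated correlation). Of 24 FOXO target genes 8 fell, 15 adjusted over the list alone (adjusted p = 0.00947 with an estimated correlation). Pik3ip1 fell by 1.55 (SE 0.18) and Txnip fell by 1.36 (SE 0.14). Cell-cycle genes shifted up with a median of 0.30. Ccne2, Cdc6 and Mcm3 rose, by 1.10 (SE 0.22), 0.87 (SE 0.18) and 0.82 (SE 0.16), and 11 of 27 members did so adjusted over the list alone (adjusted p = 0.0256 with an estimated correlation). Pkm was the 1 of 14 glycolysis genes that rose, by 0.79 (SE 0.15). Adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.038 with an estimated correlation). The call of the glycolysis list ended without genes below the median signal (median 0.234, adjusted p = 0.0586). Rag1, Rag2 and Xrcc6 were the recombination genes that fell (3 of 12, adjusted p = 0.304 with an estimated correlation). Jun, Btg2 and Klf6 were the immediate early genes that fell (3 of 19, adjusted p = 0.399 with an estimated correlation). Ribosomal protein genes had a median of 0.22 and no member past the threshold (adjusted p = 0.304 with an estimated correlation).

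Among markers of other cell types, Ctsg and Prtn3 rose of the 18 granulocyte and monocyte genes in FOXO1-deficient cells (2 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation). The list lost its call without FOXO1-deficient replicate 2 (adjusted p = 0.648), the array with the higher neutrophil-gene median of the pair (6.89 against 5.65). Thy1 and Cd5 rose in the T-lineage list, which did not pass (adjusted p = 0.295). Klrd1, Klrb1c and Prf1 fell in the NK and innate lymphoid list, which did not pass (adjusted p = 0.8). Cd34, Mycn and Cd48 rose in the stem and multipotent progenitor list (adjusted p = 0.412), and Il7r and Irf4 fell in the list of lymphoid regulators (adjusted p = 0.295). H2-Aa and H2-Eb1, which encode class II antigen-presenting molecules, rose by 1.58 (SE 0.21) and 1.21 (SE 0.16). Their means in FOXO1-deficient cells, 8.43 and 7.69, were no higher than in the Ebf1 wild type, at 8.53 and 8.34. The plasma cell marker Sdc1 fell by 2.21 (SE 0.195). These genes belong to the mature B and plasma cell list, which did not pass (adjusted p = 0.576). The dendritic, erythroid, interferon, apoptosis and sex chromosome lists did not pass, with adjusted p of 0.415, 0.914, 0.0587, 0.8 and 0.914. The interferon list passed upward without FOXO1-deficient replicate 2 (adjusted p = 0.00213), Foxo1 wild-type replicate 2 (adjusted p = 0.0344) or either proB array (adjusted p = 0.0497). The T-lineage list passed upward without genes below the median signal (adjusted p = 0.0231), and the list of lymphoid regulators downward under quantile normalization (adjusted p = 0.0293).

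**Figure D2:**
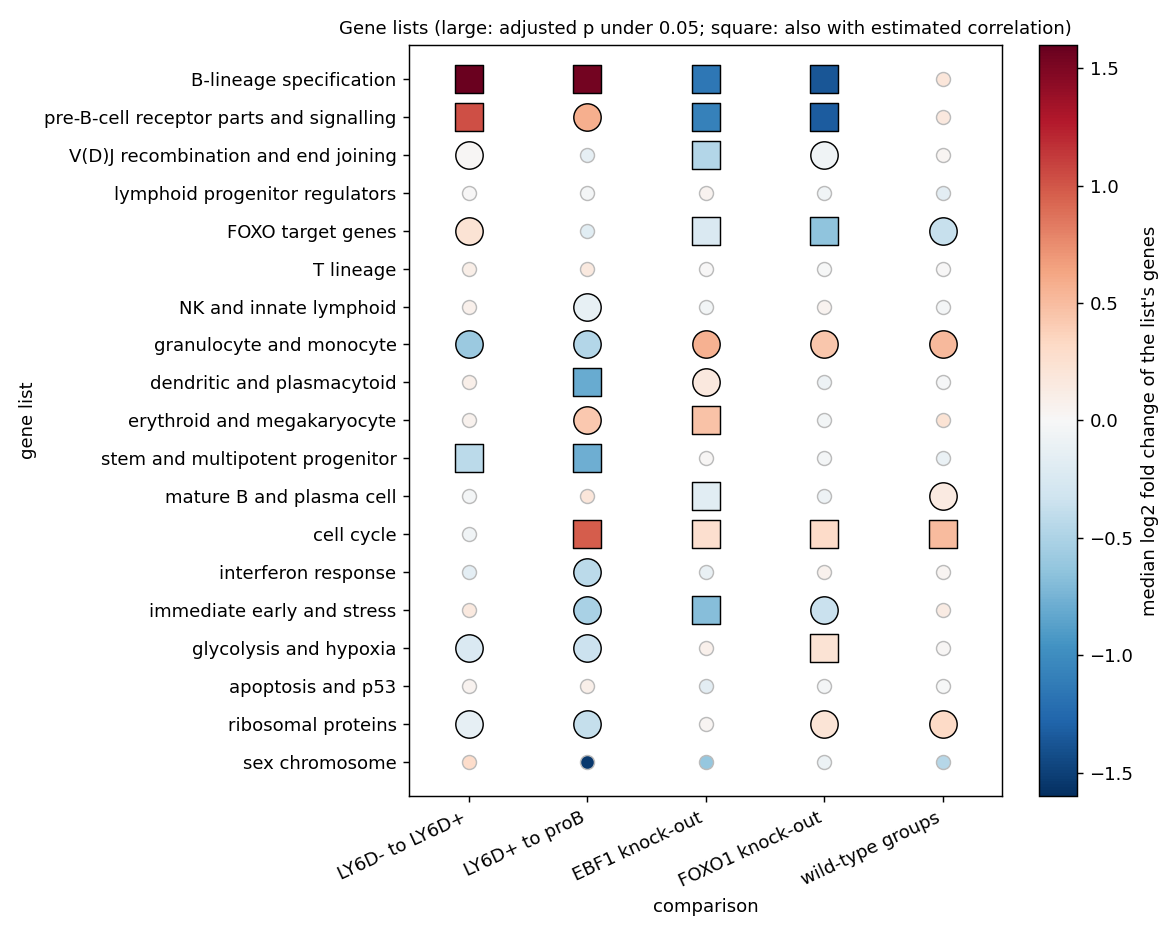
Median log2 fold change (colour) of the 19 gene lists (rows) in 5 comparisons (columns). Large symbols mark an adjusted p under 0.05 in camera with the preset correlation, squares those that also passed with an estimated one. The B-lineage list had medians of 1.59 and 1.54 along the normal steps and of -1.16 and -1.36 in the EBF1 and FOXO1 knock-outs. The columns of the normal steps, the FOXO1 knock-out and the wild types share the Foxo1 wild-type LY6D-positive arrays.

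Set against each other, the knock-outs changed 94 genes in the same direction and none in opposite directions. Of these, 27 were higher in both, against 0.582 for independent lists (Fisher's exact test across genes, p = 3.8e-39), and 67 were lower in both, against 1.66 (p = 3.71e-95). The comparisons share no array, but in the fit of all 12 they share the variance estimate of each gene. With each comparison fitted on its own 4 arrays, 7 genes were higher in both, against 0.358 for independent lists, and 38 were lower in both, against 0.907 (Fisher's exact test across genes, p = 4.6e-08 and 2.73e-55). Genes higher in both included Socs2 (3.94 without EBF1 and 3.56 without FOXO1), Lrp1 (2.21 and 2.35), Ctsg (2.0 and 3.0), Cd28 (1.76 and 2.12), Mcpt8 (1.56 and 1.92), Hemgn (1.40 and 2.18), Mycn (1.31 and 1.76) and Clec4d (1.30 and 1.35). Genes lower in both included Pou2af1, Gimap4, Pde2a, Gpat3, Igll1, Chchd10, Vpreb3 and Rag1. The 94 shared genes became 46 or 40 without EBF1-deficient replicate 1 or 2, 41 or 36 without Ebf1 wild-type replicate 1 or 2, 47 or 43 without FOXO1-deficient replicate 1 or 2, and 55 without Foxo1 wild-type replicate 2. Across all 16464 genes the log2 differences correlated with Pearson's r = 0.435 and Spearman's rho = 0.314, although genes are not independent replicates. Of the 189 genes of the EBF1 knock-out 166 had the same sign in the FOXO1 knock-out, and of the 369 genes of the FOXO1 knock-out 332 had the same sign in the EBF1 knock-out.

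**Figure D3:**
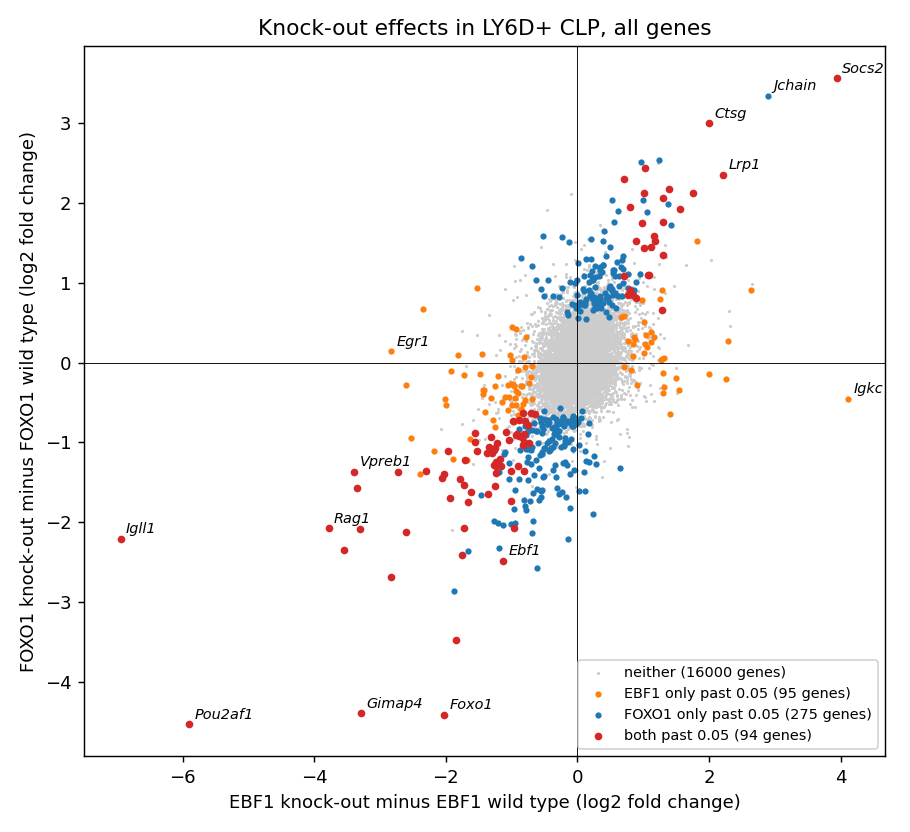
Log2 fold change of every gene without EBF1 (x axis) and without FOXO1 (y axis) in LY6D-positive CLP. Red points are the 94 genes past an adjusted p of 0.05 in both. Pou2af1 lies at -5.90 and -4.52, Igll1 at -6.94 and -2.21, and Socs2 at 3.94 and 3.56.

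The size of the effect differed between the knock-outs for 22 genes, 9 with a more positive and 13 with a more negative value without EBF1 (limma test of the difference). Igll1 fell further without EBF1, by a difference of -4.74 (SE 0.35, adjusted p = 0.00085), and so did Vpreb1, at -2.02 (SE 0.25, adjusted p = 0.034). Egr1, an immediate early transcription factor gene, differed by -2.96 (SE 0.40), with a fall without EBF1 and a value of 7.24 ± 0.25 against 7.10 ± 0.19 (SD, n = 2) in FOXO1-deficient cells and their wild type. Foxo1 differed by 2.39 (SE 0.24), having fallen further in its own knock-out. Igkc differed by 4.57 (SE 0.65), at 7.49 ± 0.44 (SD, n = 2) in EBF1-deficient and 2.35 ± 0.21 (SD, n = 2) in FOXO1-deficient cells. Cxcr4, a chemokine receptor gene of the FOXO target list, differed by 1.43 (SE 0.21). Cxcr4 was lower in the Ebf1 than in the Foxo1 wild type by no less, so this difference lies within that between the wild types. The differences for Ebf1, at 1.36 (SE 0.31), and Rag1, at -1.70 (SE 0.35), did not pass. Of the 19 lists 10 passed and none did with an estimated correlation, where their adjusted p ran from 0.0975 to 0.354. The count fell to 9 and 2 without Ebf1 wild-type replicate 1 and 2, 11 and 2 without EBF1-deficient replicate 1 and 2, 2 and 1 without Foxo1 wild-type replicate 1 and 2, and 1 and 2 without FOXO1-deficient replicate 1 and 2.

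Genes that change along the normal sequence were then followed in each knock-out. The 123 genes that rose from LY6D-negative to LY6D-positive CLP had a median of -0.86 without EBF1 (quartiles -1.24 and -0.50), and 59 of them fell (adjusted p = 1.21e-83, limma camera, and 9.47e-06 with an estimated correlation). The 63 genes that fell at that step had a median of 0.40, and 10 of them rose (adjusted p = 2.51e-14, and 0.000837 with an estimated correlation). The first median was -0.485 without LY6D-negative replicate 1, and the second was 0.224 and 0.196 without LY6D-negative replicate 1 and 2 and 0.630 without Foxo1 wild-type replicate 2. The EBF1-line arrays entered the variance behind these sets. Sets from the 8 other arrays, an alternative chosen after seeing the data, had medians of -0.991 over 73 genes and 0.526 over 41 genes (adjusted p = 8.25e-74 and 8.71e-16, and 1.36e-05 and 0.000144 with an estimated correlation). Sets fitted on their own arrays alone, a refit whose form was settled after seeing the data, held 26 and 8 genes, with medians of -1.817 and 0.871. The 1087 and 1415 genes higher and lower in proB cells had medians of 0.02 and 0.04 without EBF1 and did not pass (adjusted p = 0.682 and 0.877). Past the threshold, 44 of the 1087 fell and 8 rose, and 37 of the 1415 fell and 23 rose. With sets changed at least 2-fold the genes higher in proB cells passed in the downward direction (median -0.021, adjusted p = 0.0497).

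For FOXO1 the sets came from the Ebf1 wild type, so that no array of the FOXO1 comparison entered their log2 differences, although these arrays entered the variance. LY6D-negative CLP were measured in the Foxo1 line alone, so these sets mix the LY6D step with the difference between the lines. The CLP step gave 846 genes this way and 186 within the Foxo1 line. Their results can therefore not be read as results about the LY6D step alone. The 489 genes higher and the 357 genes lower in LY6D-positive CLP did not pass (medians 0.015 and -0.008, adjusted p = 0.449 and 0.973, limma camera). Of the 489 genes 61 fell and 12 rose, and the direction of the test was down, against the sign of the median. This result was not stable, and the genes higher in LY6D-positive CLP passed in the downward direction in several settings. Their median was -0.021 under quantile normalization (adjusted p = 0.00749), -0.097 with sets changed at least 2-fold (adjusted p = 0.00174) and -0.315 with sets and comparison fitted on their own arrays alone (119 genes, adjusted p = 3.85e-07), a refit whose form was settled after seeing the data. In sets from the 8 arrays outside the comparison, chosen after seeing the data, it was -0.081 (283 genes, adjusted p = 0.00427, and 0.112 with an estimated correlation). It was -0.054 without LY6D-negative replicate 2 (adjusted p = 0.00369), -0.106 and -0.107 without Ebf1 wild-type replicate 1 and 2 (adjusted p = 0.00132 and 0.000461) and -0.073 without FOXO1-deficient replicate 1 (adjusted p = 0.000831). The 1463 genes higher in proB cells had a median of -0.10 (adjusted p = 0.00198, and 0.0249 with an estimated correlation) and the 1850 lower ones 0.17 (adjusted p = 5.43e-07, and 0.0406 with an estimated correlation). Past the threshold, 66 of the 1463 fell and 14 rose, whereas the 1850 were evenly split, with 70 that fell and 74 that rose.

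The FOXO1 result also depended on which wild type defined the sets. With the sets of 123 and 63 genes from the Foxo1 wild type, an alternative chosen after seeing the data, the medians without FOXO1 were -0.88 and 0.79. These sets share the 2 Foxo1 wild-type arrays with the FOXO1 comparison. In 20 simulations of an unchanged knock-out against those arrays the medians were -0.0964 and 0.113, within -0.113 to -0.0563 and 0.0986 to 0.13. The observed medians of these sets lay outside both ranges. For the proB sets from the Foxo1 wild type the observed medians were 0.0602 and -0.0277, and the simulated ones 0.0645 and -0.0459. The first observed median lay within the simulated range of 0.0542 to 0.0706, the second outside that of -0.0528 to -0.0364. Simulated noise was independent between genes, so all these ranges may be too narrow.

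The wild-type LY6D-positive groups, which passed the same gate, also differed from each other. In the Ebf1 wild type Chil3 was 5.16 (SE 0.58) higher than in the Foxo1 wild type, Phf11d 2.93 (SE 0.45), Rbm45 2.79 (SE 0.21) and Tjp1 2.75 (SE 0.25). Hemgn, Pclaf and Pi4kb were 1.98, 1.97 and 1.95 higher. Btbd11 was lower, at -2.62 (SE 0.46), as were Pggt1b at -1.94 (SE 0.17), Msi2 at -1.74 (SE 0.16) and the clock gene Per1 at -1.61 (SE 0.21), with Ctnnd2, Ebi3 and Tbl1x between -1.61 and -1.56. Igll1 and Vpreb1 were 1.32 (SE 0.24) and 1.15 (SE 0.18) higher, and Ebf1 and Foxo1 did not pass, at -0.08 (SE 0.22) and -0.43 (SE 0.17). In limma 473 genes changed, 311 higher and 162 lower in the Ebf1 wild type, and 192 of them by at least 2-fold. The count was 77 or 85 without Ebf1 wild-type replicate 1 or 2, 143 or 49 without Foxo1 wild-type replicate 1 or 2, 277 without either FOXO1-deficient array, and 29 when the 4 wild-type arrays were fitted alone.

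Cell-cycle genes were higher in the Ebf1 than in the Foxo1 wild type, with 8 of 27 past the threshold, 22 adjusted over the list alone, and a median of 0.50 (adjusted p = 4.34e-18, limma camera, and 0.013 with an estimated correlation). Cdk1 and Ccnb2 were 1.16 (SE 0.13) and 1.26 (SE 0.16) higher. Of 24 FOXO target genes 4 were lower, with Cxcr4 at -1.56 (SE 0.15) and Txnip at -1.06 (SE 0.14). Adjusted over the list alone 6 were lower and 1 higher (adjusted p = 0.231 with an estimated correlation). H2-Aa, H2-Ab1 and H2-Eb1 were higher by 1.68 to 1.86 in the mature B and plasma cell list and Sdc1 was lower (adjusted p = 0.207 with an estimated correlation). Of 11 ribosomal protein genes Rps9, Rps15 and Rps27 were higher and Rps6 lower (adjusted p = 0.291 with an estimated correlation). The granulocyte and monocyte list had a median of 0.52 and no member past the threshold over all genes, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.506 with an estimated correlation). The other 14 lists did not pass. Among them the B-lineage list, with Igll1, Vpreb1, Vpreb3 and Spib higher, had an adjusted p of 0.0536. It passed upward with the replicate number as a block (adjusted p = 0.047), without either EBF1-deficient array (adjusted p = 0.0469), without Ebf1 wild-type replicate 2 (adjusted p = 0.026) and without Foxo1 wild-type replicate 2 (adjusted p = 0.0193). On the same arrays the log2 signal of the 3' control probe set of Gapdh exceeded that of its 5' one by 3.58 ± 0.161 in the 4 Ebf1-line arrays (SD, n = 4) and by 5.51 ± 0.496 in the other 8 (SD, n = 8). For b-actin the excess was 3.04 ± 0.22 and 4.2 ± 0.279, for the transferrin receptor 3.41 ± 0.338 and 2.88 ± 0.605, and for pyruvate carboxylase 0.058 ± 0.0688 and 0.11 ± 0.236, with overlapping ranges for the last 2.

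**Figure D4:**
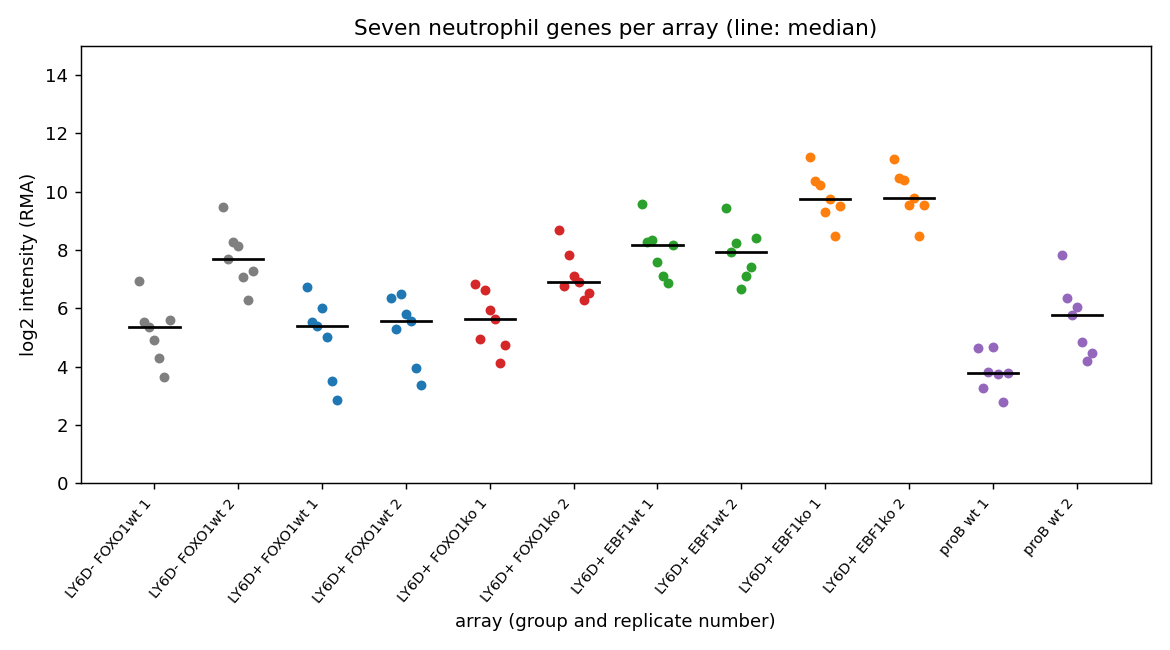
Log2 signal (y axis) of 7 neutrophil genes on each of the 12 arrays (x axis), 1 point per gene and a line at their median. The medians were 9.76 and 9.77 in the EBF1-deficient, 8.17 and 7.93 in the Ebf1 wild-type and 5.39 and 5.55 in the Foxo1 wild-type LY6D-positive arrays, and 5.35 and 7.69 in the LY6D-negative arrays.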

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

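The tests of EBF1 loss on neutrophil genes, of control transcripts and of Ly6d were chosen only after the results were seen, as were the reading of the list of 12 granulocyte genes, the share among genes chosen without the knock-out arrays and the comparison of LY6D-negative cells with the Ebf1 wild type. The other tests were set before their values were seen. A correlation among the neutrophil genes themselves decided nothing, since these genes had been picked on such values.

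The knock-out effects differed, by a limma test of the difference, for Igkc (4.57), Foxo1 (2.39), Car1 (2.14), Sdc1 (2.06), Cd177 (2.02) and Btbd3 (1.97), which had more positive values without EBF1. They differed for Igll1 (-4.74), Rundc3b (-3.02), Egr1 (-2.96), Htra3 (-2.45), Myl4 (-2.32) and Cd300lb (-2.16), which had more negative values without EBF1. Lists whose effects differed with the preset correlation were, by median difference, B-lineage specification (-0.32), pre-B-cell receptor parts (-0.119), immediate early genes (-0.132), mature B and plasma cell genes (-0.168), interferon response (-0.276), glycolysis (-0.29) and ribosomal proteins (-0.291). More positive without EBF1 were FOXO targets (0.309), erythroid and megakaryocyte genes (0.314) and dendritic genes (0.236). The FOXO target list was lower in the Ebf1 than in the Foxo1 wild type, with a median of -0.367. Its difference of effects can therefore not be told apart from the gap between the wild types. None of these 10 passed with an estimated correlation. Leaving out 1 array moved some of the medians, given here with the sign of the test. Immediate early genes went to -0.005 without Ebf1 wild-type replicate 2 and -0.308 without EBF1-deficient replicate 1. Pre-B-cell receptor parts went to -0.030 without EBF1-deficient replicate 2, and interferon response to -0.126 without FOXO1-deficient replicate 1. The 842 probe sets without a gene name here held 10 past the threshold in the EBF1 and 14 in the FOXO1 comparison.

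Neutrophil genes (S100a8, S100a9, Ngp, Camp, Ltf, Lcn2 and Chil3, of which 5 are in the granulocyte and monocyte list) were highest in the EBF1-deficient arrays, with S100a8 at 11.17 ± 0.05 (SD, n = 2). Arrays without EBF1 loss also differed in the 7 genes. The median difference was 2.7 (SD over genes 1.26) between the wild-type groups and 2.66 between the LY6D-negative replicates. These genes were picked after such values were seen, and of the 7 Chil3 alone passed between the wild types. The values therefore cannot decide whether EBF1 loss alone raised them. RNA of granulocytes carried into the sort remains a candidate explanation, although GR1 and MAC1 were gated out. A list of 12 other granulocyte genes had median differences of 0.0315 between the LY6D-negative replicates (7 of 12 positive), 0.354 between the wild-type groups (9 of 12) and 0.322 without EBF1 (10 of 12). The first lay below the bound set for rejecting the idea, but these genes were near the low end of the scale in LY6D-negative CLP (median 4.26, under the 4.87 of all genes), so this test cannot decide.

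The wild-type LY6D-positive groups differed in 473 genes, and in 29 when these 4 arrays were fitted alone. A difference carried by the whole Ebf1 line of arrays fits: 418 of the 473 (88.4%, 95% exact interval 85.1 to 91.1) had the same sign between the EBF1-deficient and FOXO1-deficient arrays. These arrays entered the variance behind the 473, and of 164 genes called without them 147 (89.6%, 83.9 to 93.8) had the same sign. Both intervals treat genes as independent, which they are not, and do not measure the spread between arrays. RNA amplification or degradation is one candidate source, as the 3' excess differed by -1.93 for Gapdh and -1.16 for b-actin without overlap, but by 0.526 for the transferrin receptor and -0.0518 for pyruvate carboxylase with overlap. It cannot be told apart from strain, transplantation or batch, because no other line was measured both ways. EBF1-deficient marrow came from transplanted hosts and the sources used here do not say whether its wild type did, so transplantation stays open for the EBF1 comparison too.

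The knock-outs shared 94 changed genes, of 189 without EBF1 and 369 without FOXO1. LY6D-negative cells inside the LY6D-positive gate are argued against by Ly6d, whose lower change of the pair was -0.119 (SE 0.27), while Igll1 in EBF1-deficient cells (3.79) was as low as in LY6D-negative cells (4.27). A return to the LY6D-negative state as the whole cause is argued against too. Of the 126 genes lower without EBF1, 88.1% were lower in LY6D-negative than in LY6D-positive CLP, but 61.9% (95% exact interval 52.8 to 70.4) by at least 0.5 of the knock-out change. Of the 63 higher ones 65.1% were higher there, and 36.5% (24.7 to 49.6) by that much. With the Ebf1 wild type as LY6D-positive CLP the shares were 68.3% (59.4 to 76.3) and 23.8% (14 to 36.2), but LY6D-negative cells were measured in the Foxo1 line alone. The intervals of these shares also treat genes as independent and do not measure the spread between arrays. Socs2 was 10.19 ± 0.09 (SD, n = 2) in EBF1-deficient cells but 6.08 ± 0.33 (SD, n = 2) in LY6D-negative CLP. What else sets these cells apart was not tested.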

How the results depend on the processing

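Some results on targeted genes and stage sets kept their direction and side of the threshold. They did so under every alternative set before the data were examined and run on them. These were Foxo1 in its own knock-out, the stage sets in the EBF1 knock-out from the CLP step, and the FOXO1 proB sets from the Ebf1 wild type. Medians ran from -1.111 to -0.485 and 0.196 to 0.630 for the EBF1 sets. For stage sets the refit on their own arrays took its form after the data were seen, and gave -1.817 and 0.871. The 353 results of named genes stayed the same in 6499 of 7000 settings, lost the call in 448, gained it in 53 and reversed in none. Named genes were picked as anchors, as largest changes or by smallest p in a list. Their share therefore does not describe the called genes in general, whose counts moved more. List results stayed the same in 2258 of 2388, lost the call in 107, gained it in 22 and reversed in 1, the erythroid list of the knock-out difference (-0.090 without genes below the median). The B-lineage list kept its call and direction in both knock-outs and both normal steps under every alternative run on lists. So did the lists of pre-B-cell receptor parts, FOXO targets and cell cycle in both knock-outs. Unless a smaller number of arrays or genes accounts for it, the cause was not tested. A 2-fold minimum gave 124 genes for EBF1, 211 for FOXO1, 121 between the CLP stages, 1182 to proB, 192 between wild types and 60 shared. Fitting the compared arrays alone, with 2 residual degrees of freedom, gave 86 for EBF1, 34 between the CLP stages, 29 between wild types and 45 shared, and ended the Ebf1 call (-1.12, adjusted p = 0.0755). Array weights gave 845 for FOXO1 and 725 between wild types. The Ebf1 wild type as LY6D-positive CLP gave 846 genes between the CLP stages, and both wild types as control gave 836 for EBF1. With an estimated correlation 21 of the 54 list results passed.

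In the FOXO1 knock-out the genes higher in LY6D-positive CLP passed downward at -0.021 under quantile normalization (adjusted p = 0.00749), -0.097 with 2-fold sets (adjusted p = 0.00174), -0.315 with the compared arrays fitted alone and -0.081 with sets from arrays outside the comparison (chosen after seeing the data), and in 4 fits without 1 array. With sets from the Foxo1 wild type (chosen after seeing the data) they were at -0.884, the genes lower in LY6D-positive CLP at 0.792, and the genes higher and lower in proB cells at 0.060 and -0.028. In the EBF1 knock-out the genes higher in proB cells passed downward at -0.021 with 2-fold sets (adjusted p = 0.0497). With each array left out in turn the counts ran from 66 to 196 for EBF1, 104 to 434 for FOXO1, 61 to 245 between the CLP stages, 1561 to 2639 to proB, 49 to 556 between wild types, 1 to 21 for the difference and 36 to 100 shared, the last lowest without Ebf1 wild-type replicate 2. The Ebf1 change ran from -1.295 to -0.953, and the FOXO1 median of genes higher in LY6D-positive CLP from -0.107 to 0.1.

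Replicate numbers showed no pairing across all genes: deviations of same-numbered arrays correlated between -0.0815 and 0.0756 over 15 pairs of groups. This cannot exclude a batch that touches few genes. All 7 neutrophil genes were higher in replicate 2 of LY6D-negative CLP, FOXO1-deficient CLP and proB cells (medians 2.66, 1.79 and 1.41). In the EBF1-deficient, Ebf1 wild-type and Foxo1 wild-type LY6D-positive groups 5, 3 and 4 of the 7 were. With the number as a block the counts were 171 for EBF1, 347 for FOXO1, 159 between the CLP stages, 2410 to proB, 399 between wild types and 19 for the difference, and Ebf1 (-1.12) had an adjusted p of 0.0572. Averaging probe sets gave no value, since each gene had 1. Median centring and quantile normalization moved the median of all genes by less than 0.1 in each contrast. Signal over background was not measured here, so it is not known which dim genes were detected.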

Other observations

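The genes, families and values here were chosen after the data were seen. All 8 measured Gimap genes, a cluster of GTPases that act in lymphocyte survival, fell without FOXO1, from 0.96 for Gimap5 to 4.39 for Gimap4 in size, with a family median of -1.76 (-1.73 and -1.86 under the other scalings). Without EBF1, Gimap4, Gimap5 and Gimap8 fell, by 3.29 (SE 0.42), 1.04 (SE 0.18) and 1.85 (SE 0.20). From LY6D-negative to LY6D-positive CLP 4 of the 8 rose, Gimap3, Gimap4, Gimap5 and Gimap8, and from LY6D-positive CLP to proB cells 5 fell, with Gimap7 down by 2.58 (SE 0.24). Both steps and the FOXO1 comparison use the same Foxo1 wild-type arrays, so these changes are not independent. The test of the difference between the knock-outs passed for none of the 8.

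Class II antigen presentation genes did not move together. H2-Aa and H2-Eb1 rose without FOXO1, by 1.58 (SE 0.21) and 1.21 (SE 0.16), from 6.85 and 6.48 to 8.43 and 7.69. They were no lower in the Ebf1 wild type, at 8.53 and 8.34, so these changes lie within the difference between the wild types. H2-Ob, part of the peptide-loading regulator H2-O, fell by 1.65 (SE 0.13) without FOXO1 and by 1.36 (SE 0.13) without EBF1. In proB cells the loading chaperone genes H2-DMa and H2-DMb1 were lower than in LY6D-positive CLP, by -3.81 (SE 0.15) and -3.31 (SE 0.29). Jchain stood at 6.33 ± 0.17 and 6.71 ± 0.30 (SD, n = 2) in EBF1- and FOXO1-deficient cells and at 3.43 ± 0.02 and 3.37 ± 0.41 (SD, n = 2) in their wild types, and Igkc at 7.49 ± 0.44 in the EBF1-deficient cells. The Jchain change without EBF1, 2.90 (SE 0.63), did not pass (limma adjusted p = 0.064). Ighm differed by -0.11 (SE 0.18) and -0.36 (SE 0.18) and passed in neither knock-out. Ighg2b was lower past the threshold in both, at -1.71 (SE 0.27) without EBF1 and -1.22 (SE 0.27) without FOXO1. Iglc1 and Ighg1 passed in neither.

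The proB arrays differed in sex-linked genes. Xist was at 3.85 in replicate 1 and 11.45 in replicate 2, and the Y-linked Eif2s3y at 8.28 and 2.05. These values argue against the proB replicates being repeat measurements of the same RNA. In the 10 CLP arrays Xist lay between 8.76 and 11.23 and Eif2s3y between 4.06 and 8.14.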
